A study of Gallus gallus
Homo sapiens with 4 samples.

How the data were processed

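RNA was measured in BxPC3 xenografts on the chick chorioallantoic membrane, the vascular membrane that lines the shell of the developing egg. BxPC3 is an established human cell line from a pancreatic ductal adenocarcinoma. Per the labels' protocols, the cells were placed on the intact membrane of eggs kept at 37.8 °C and 75% humidity, and the membranes were excised and snap-frozen. RNA of 3 membranes was pooled at 1 day and again at 6 days after grafting. Each pool was hybridised to 1 human and 1 chicken Affymetrix array, which gave 4 arrays in 4 groups with 1 array per group. The membranes were taken at embryonic day 11 for the first time point and at embryonic day 16 for the other.

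The deposited values are intensity values, 1 signal per probe set on a linear scale, and the software named in the submitters' processing notes is GCOS 1.2. The 2% trimmed mean of each deposited column lay at 100, as tested on the values themselves. The scaling options, background settings and masks that the authors used are not given in the sources used here. Detection calls are not used here.

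The human table held 54675 probe sets, of which 62 were controls. Through the platform annotation, 41091 probe sets carried 1 gene symbol, 1801 carried several and 11721 carried none. The chicken table held 38535 probe sets with 96 controls, and 27168 carried 1 symbol, 177 several and 11094 none. Symbols of 26863 chicken probe sets were looked up again through their Entrez identifiers in a RefSeq gene table of the GRCg7b assembly, from which no coordinates were taken. Probe sets with several symbols or none, and all controls, were left out of the gene results. Members of the gene lists were also matched through older symbols.

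Each pair of arrays was scaled to the same 2% trimmed mean. Signals below a floor were then set to the floor, which was the 50th percentile of the non-control probe sets averaged over both arrays, 57.2 for the human and 46.6 for the chicken arrays. Values were taken to log2 after that. A gene was represented by the probe set with the highest mean log2 signal, and it counted as measured when that probe set lay above the floor on at least 1 array. Ratios named below are those of this probe set, and other probe sets of the gene can differ. Where 1 side lay at the floor, the ratio is a bound and is written as at least N-fold. Such genes entered list medians at their bound. The human and chicken tables were normalized separately, so no level was compared across them.

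With 1 array per time point there was no test between time points and no p-value was computed. Genes were counted by a size rule of 2-fold or more. For each gene list with 5 or more measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 10 bins. A list was called lower below the 2.5th percentile and higher above the 97.5th, as a description of these arrays only. The standard deviation of the log2 ratio between probe sets of 1 gene, the technical spread that single arrays allow, was 0.75 over 3459 human genes and 0.63 over 2520 chicken genes. It leaves out the spread between membranes and between arrays, and the number of arrays limits the precision of every value.

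The genes named in the report were chosen by a rule. It takes the 10 genes higher and the 10 genes lower with the largest ratios among genes above the floor on both arrays whose other probe sets did not go the opposite way. It adds up to 4 members of each list with the largest ratios of 2-fold or more, and always NTN1, UNC5B, NEO1, VEGFA and MKI67. The rule, the 23 lists for the human arrays, the 23 lists for the chicken arrays and the alternatives were fixed before the data were examined. After the data had been seen, 3 further human lists were added, along with a scaling to the hybridisation spike-ins and a minimum of 4 times the floor for the brighter array. The alternatives fixed beforehand were the values as deposited, median scaling, quantile normalization, loess normalization, a floor at the 25th or 75th percentile, no floor, the floor as a pseudocount, the mean of all measured probe sets, leaving out probe sets with the suffixes x or s, and a 3-fold size rule. List calls were repeated under 11 alternatives, which were these without the 3-fold size rule, as it does not enter list medians, plus the spike-in scaling chosen after the data had been seen.

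The procedure was tested on simulated data. For the human arrays, with 15766 genes, 70% of genes simulated at 4-fold and 86% of those at 8-fold were recovered, and 14.4% of unchanged genes passed the size rule. For the chicken arrays, with 10775 genes, these shares were 72%, 91% and 9.79%. Of 200 simulated unchanged lists of 20 genes, 4% were called apart on the human arrays, and the share was also 4% on the chicken arrays. These lists were drawn at random from the simulated genes, so a share near this was set by the cut-offs. The simulation used independent genes and only the spread between probe sets. It left out the spread between arrays and pools, trends with signal and genes that move together. The shares are therefore not error rates for these arrays. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.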

Results

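Transcript levels were measured in BxPC3 pancreatic cancer xenografts and the chick membrane that carried them, 1 day and 6 days after grafting. The same pooled RNA of 3 membranes was read on a human array for the tumour cells and on a chicken array for the host tissue. The series was designed to find genes tied to tumour invasion and angiogenesis. There were no replicates, so all ratios below compare 1 array with another and carry no p-value. On the human arrays 46.7% of probe sets lay above the signal floor on day 1 and 52.4% on day 6, and on the chicken arrays 54.3% and 44.1%.

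In the grafted human cells, genes of the amino acid and endoplasmic reticulum stress response had much lower signals on day 6 than on day 1. TRIB3, a pseudokinase induced by this response, was at least 34.7-fold lower, and ASNS, which makes asparagine, was at least 27.8-fold lower. DDIT3, a transcription factor of endoplasmic reticulum stress, was 5.80-fold lower, and SLC7A11, a cystine transporter, was 5.62-fold lower on its brightest probe set, while its other probe set above the floor had a log2 ratio of 0.85. Of 22 measured genes of the list, 14 were lower by 2-fold or more and 1 was higher. The list median was -2.09 on the log2 scale, below all 10000 matched random lists, and the call held under each of the 11 alternatives.

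Immediate early genes and inflammatory genes of the human cells were lower on day 6 as groups. Of 18 immediate early genes 10 were lower and 1 was higher, with a median of -1.32 that lay below all 10000 random lists. The call held under each of the 11 alternatives, but the median was -0.74 under quantile and under loess normalization. Without probe sets of suffix x or s it was -0.73, at percentile 2.475, just inside the cut-off. DUSP5, a phosphatase that acts on ERK, was 12.9-fold lower, MYC was 4.08-fold lower and EGR1 was 3.59-fold lower on its brightest probe set, while its probe sets ranged from -1.84 to 0.45. The brightest probe set of DUSP1 was at least 22.7-fold lower, but its other probe sets above the floor had higher signals, and its log2 ratio was 1.39 under quantile normalization. Of 25 cytokine and inflammation genes 11 were lower and 2 were higher, with a median of -0.78 at percentile 0.02. CXCL8, which attracts neutrophils, was 3.71-fold lower on its brightest probe set and had a log2 ratio of -0.62 on its other. IL1B was at least 3.72-fold lower. CCL5 went the other way, at least 4.14-fold higher, as did NOS2, at least 3.85-fold higher.

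Interferon response genes of the human cells had a median of -0.69 at percentile 0.03, with 7 of 30 lower and 2 higher. ISG15, a ubiquitin-like modifier, was 11.5-fold lower, IFI27 was 5.36-fold lower, OAS1 was at least 4.18-fold lower and IFI6 was at least 2.98-fold lower. The other OAS1 probe set had a log2 ratio of -0.60. The call for the interferon list was lost with the floor at the 75th percentile, where the median was -0.39.

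Glycolysis and hypoxia genes of the human cells were lower on day 6 in the chosen setting, by an amount that depended on the normalization. Of 21 glycolysis genes 9 were lower and 2 were higher, with a median of -0.96 at percentile 0.12. The hexokinases HK1 and HK2 were at least 10.3-fold and at least 6.87-fold lower, the glucose transporter SLC2A1 was 4.64-fold lower and PFKFB3 was at least 4.25-fold lower. Of 22 hypoxia response genes 10 were lower and 4 were higher, with a median of -0.87 at percentile 0.61. VEGFA, the main growth factor for endothelial cells, had a signal of 4133 on day 1 and 484 on day 6, which was 8.53-fold lower, and all its other probe sets were lower too. DDIT4, an inhibitor of mTOR signalling, was 10.4-fold lower and ADM, a vasodilator peptide, was 7.32-fold lower. The glycolysis call was lost under quantile normalization, loess normalization and without probe sets of suffix x or s, where the medians were -0.17, -0.11 and -0.25. The hypoxia call was lost under quantile normalization, with a median of -0.29, and with the floor as a pseudocount, with a median of -0.47, and its median was -0.41 under loess normalization.

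Netrins and their receptors were higher as a group on the human arrays in the chosen setting. Of 15 measured members 8 were higher and 2 were lower, and the median was 1.01 at percentile 99.14. For 7 of the 15 the ratio was a bound, and the median was the bound of NTN4, with signals of 45.5 and 115. UNC5C was at least 3.56-fold and DSCAM at least 2.86-fold higher. UNC5C had a log2 ratio of -0.60 with the floor at the 25th percentile. Whether a higher background of dim probes on day 6 raised this list was not tested. NTN1, the guidance cue netrin-1, was 3.99-fold higher, from a signal of 57.8 just above the floor to 231, and its other probe set above the floor had a log2 ratio of 0.94. NEO1, a netrin receptor, was at least 2.77-fold higher on its brightest probe set, while a further probe set was lower and spike-in scaling gave -1.34. The receptor UNC5B had a log2 ratio of -0.51, and its probe sets ranged up to 1.16. ITGA3, an integrin subunit, was 3.99-fold lower. The netrin call was lost with the floor at the 75th percentile, with no floor, with the mean of all probe sets and under spike-in scaling, where the medians were 0.28, 0.51, 0.60 and 0.13. Mural and smooth muscle markers share some members, such as MYL9, with the mesenchymal list, and whether the grafted cells supply them was not tested. They were higher beside the netrins, with 9 of 16 members higher, none lower and a median of 1.16 at percentile 99.47. Of these, ACTG2 was at least 6.08-fold, RGS5 at least 4.04-fold and MYL9 at least 3.98-fold higher, and the call was lost under quantile and loess normalization and with the floor at the 75th percentile, where the medians were 0.57, 0.58 and 0.47.

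Ribosomal protein genes of the human cells had a median of -1.27 at percentile 0.08, with 16 of 22 lower, but the median was 0.00042 under quantile and 0.21 under loess normalization and the call was lost under both. RPL19 was 3.83-fold lower. RPS6 was 4.28-fold lower on its brightest probe set, but its log2 ratio was 0.25 without probe sets of suffix x or s.

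The 14 other human lists lay within the range of random lists in the chosen setting. Cell cycle genes had a median of -0.10 at percentile 81.0, with 31 of 38 within 2-fold, 5 lower and 2 higher. KIF20A was 3.68-fold lower, BUB3 was 2.38-fold lower but had a log2 ratio of 1.61 without probe sets of suffix x or s, CENPF was 3.71-fold lower on its brightest probe set but had 0.55 on the log2 scale on another, and CDCA7 was 2.36-fold higher. MKI67, a proliferation marker, was 2.11-fold higher on its brightest probe set, and its probe sets ranged from -0.83 to 1.36. Secreted angiogenesis regulators had a median of 0.23, with 9 of 28 higher and 6 lower. PDGFB was 4.53-fold and ANGPTL4 at least 3.76-fold higher, while VEGFA and ADM, named above, were lower by the largest ratios of the list. Matrix proteases and inhibitors had a median of -0.06, with 3 of 34 higher and 7 lower. The collagenase MMP1 was 8.92-fold lower and KLK6 was 3.16-fold higher. MMP16 was 3.80-fold higher on its brightest probe set, but its other probe set above the floor on both arrays had a log2 ratio of 0.13. Epithelial junctions and keratins had a median of -0.41 at percentile 66.5, with 9 of 24 lower and 2 higher. JUP was 5.37-fold, OCLN 3.94-fold and CLDN4 at least 5.59-fold lower, while CLDN3 was at least 3.37-fold higher. Pancreatic ductal adenocarcinoma markers had a median of -0.20, with 7 of 35 lower and 3 higher, S100P 3.23-fold lower and the mucin MUC5AC 2.65-fold higher. Squamous differentiation genes had a median of -0.10, with 2 of 23 higher and 2 lower, among them KRT4, 2.23-fold higher, CSTA, 2.16-fold lower, and KRT15, 2.05-fold lower. Mesenchymal genes had a median of 0.56, heat shock genes -0.85, cholesterol synthesis genes -0.43 and oxidative phosphorylation genes -0.62. Among markers of other cell types, the medians were 0.72 for collagens and fibroblast matrix, 0.54 for endothelial cells, 0.48 for erythroid cells and 0.33 for leukocytes. Under some of the 11 alternatives lists of this group were called higher, collagens and fibroblast matrix under 5, endothelial cells under 3, squamous differentiation under 2 and erythroid cells under 1.

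Of 15766 measured human genes 3067 were higher on day 6 and 2134 were lower by 2-fold or more, of which 1242 and 1381 were above the floor on both arrays. The lower genes with the largest ratios under the naming rule, which takes genes above the floor on both arrays, were bright on day 1. That rule favours bright genes here, as the day 6 signal also had to exceed the floor. TRIB3, named above at no less than 34.7-fold, falls outside it. GDF15, a stress-induced cytokine, was 30.1-fold lower and ERRFI1, an inhibitor of the EGF receptor, was 14.2-fold lower. MAFF was 16.7-fold lower on its brightest probe set and had a log2 ratio of -1.46 on its other. The metallothioneins MT1X, MT1HL1, MT1H and MT1G were 16.4-fold, 16.3-fold, 13.9-fold and 13.5-fold lower, and the histone genes H2AC25 and H2BC21 were 13.1-fold and 12.3-fold lower. The other H2AC25 probe set had a log2 ratio of -1.27. The metallothionein and histone families have near-identical members that share probes, so which member was measured is uncertain. The higher genes with the largest ratios under the same rule were dim on day 1. Examples were L3MBTL1, 8.84-fold higher from 63.4, FUZ, 7.73-fold higher from 63.9, and the R-spondin receptor LGR6, 6.45-fold higher from 127. The others were LINC02232 at 7.23-fold, FCGR2C at 6.74-fold, NUDT16 at 6.14-fold, ITM2C at 6.02-fold, NOVA1 at 6.01-fold, RUBCN at 5.81-fold and TNFRSF14-AS1 at 5.54-fold. Another TNFRSF14-AS1 probe set above the floor had a log2 ratio of 0.70. Higher genes made up 59.0% of the human genes past the size rule. The share was 34.3% with the floor at the 75th percentile, 40.8% with the brighter array at 4 times the floor and 29.9% under spike-in scaling. Spike-in scaling moved the median log2 ratio of all genes from 0.11 to -0.32.

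**Figure D1:**
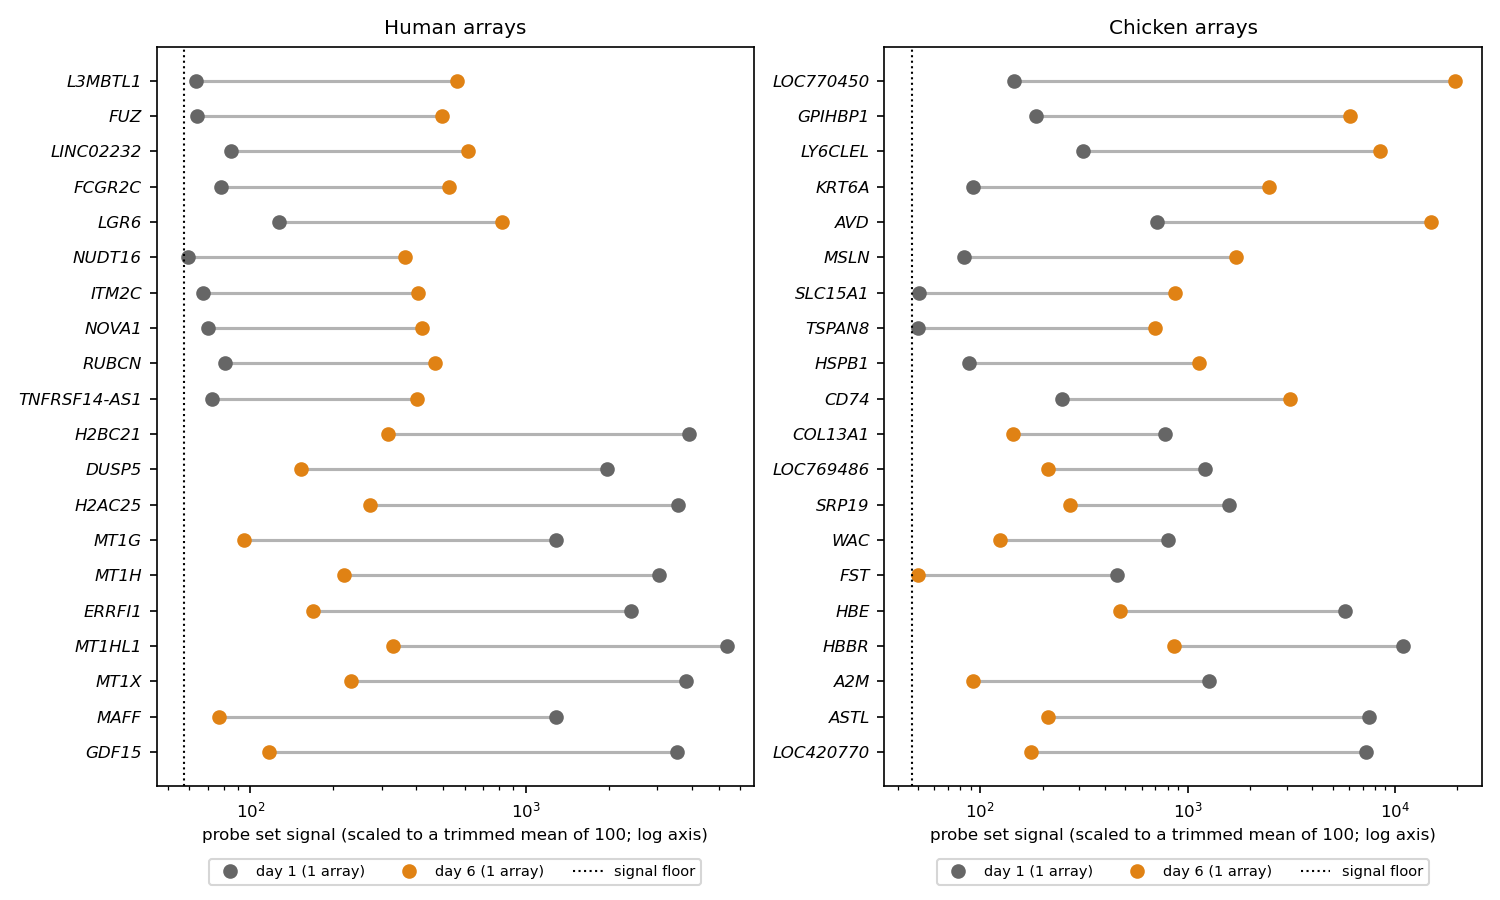
Probe set signals (log axis, scaled to a trimmed mean of 100) on day 1 and day 6, 1 array each, for the 10 higher and 10 lower genes with the largest ratios under the naming rule on the human and chicken arrays, with the signal floor dotted. The human higher genes start between 59.1 for NUDT16 and 127 for LGR6, against a floor of 57.2, while chicken AVD goes from 708 to 14896.

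In the chick membrane, immune, keratin and smooth muscle genes had higher signals on day 6, and embryonic globins and cell cycle genes had lower ones. The membrane was also 5 embryonic days older, so time with the graft and embryo age cannot be told apart in any of these values. Of 24 measured genes of the leukocyte list 12 were higher and 3 were lower, with a median of 0.97 above all 10000 random lists. For 10 of the 24 the ratio was a bound, and whether leukocyte numbers changed was not tested. AVD, the biotin-binding protein avidin, went from a signal of 708 to 14896, and CD74, the invariant chain of class II antigen presentation, was 12.7-fold higher. The class II gene BLB1 was 12.0-fold higher on its brightest probe set and had a log2 ratio of 0.93 on another. The lysozyme gene LYZ was at least 11.6-fold higher. Of 19 cytokine and inflammation genes 6 were higher and none was lower, with a median of 0.55 at percentile 99.86. The acute phase gene SAA was at least 5.57-fold, the lipocalin EXFABP 5.26-fold, the prostaglandin synthase PTGS2 4.98-fold and NFKBIA, an inhibitor of NF-kappaB, 3.65-fold higher.

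Keratins and cornified layer genes of the membrane had a median of 1.33 above all 10000 random lists, with 10 of 15 higher and none lower. KRT6A was 26.9-fold higher, KRT5 at least 8.37-fold, the cell envelope protein PPL 6.83-fold and KRT13 6.20-fold. Epithelial junctions and keratins, a list that shares members with it, had 8 of 20 higher and none lower, with a median of 0.75 at percentile 99.91. JUP was 4.31-fold, CLDN3 3.48-fold, the transcription factor ELF3 3.43-fold and the desmosomal protein DSP 3.01-fold higher. The other JUP probe set had a log2 ratio of 0.88. Mural and smooth muscle genes had 8 of 12 higher and none lower, with a median of 1.14 at percentile 99.98. ACTG2, a smooth muscle actin, was 11.9-fold higher, TAGLN 6.12-fold and MYH11, smooth muscle myosin, 3.04-fold. MYLK was 3.05-fold higher on its brightest probe set, while its probe sets ranged from -0.45 to 1.61. The leukocyte, cytokine, keratin, junction and mural calls held under each of the 11 alternatives.

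Cell cycle genes of the membrane had a median of -0.43 below all 10000 random lists, and the list stayed below its random lists under spike-in scaling, where its median turned to 0.49. Of 34 members 5 were lower and none was higher, among them CENPF at least 3.63-fold, NDC80 2.83-fold, PLK1 2.32-fold and MCM5 2.24-fold lower, while MKI67 had a log2 ratio of -0.14. Erythroid genes had a median of -0.55 below all 10000 random lists, which turned to 0.37 under spike-in scaling, and the call was lost under quantile normalization. The embryonic globin genes HBZ, HBBR and HBE were at least 19.2-fold, 12.6-fold and 12.2-fold lower, and 8 of the 12 members lay within 2-fold.

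Secreted angiogenesis regulators of the membrane had a median of 0.35 at percentile 98.31, with 6 of 25 higher and 3 lower, but 7 of the 11 alternatives ended the call. VEGFD, a lymphatic growth factor, was at least 22.9-fold higher and FGFBP1, which releases stored fibroblast growth factor, was 3.41-fold higher, while HGF was 3.05-fold and FGF1 at least 2.55-fold lower. Matrix proteases and inhibitors had a median of 0.54 at percentile 99.27, with 5 of 23 higher and 3 lower, and 6 alternatives ended the call. SERPINB5 was at least 9.08-fold, the cathepsin CTSK 3.51-fold and TIMP2 2.55-fold higher. Mesenchymal genes had a median of 0.67 at percentile 99.62, with 6 of 19 higher and 4 lower. The call was lost with the mean of all probe sets, where the median was 0.44. This list shares members with the mural list, among them TAGLN, named above, so the results of these lists are not independent. LOX, which crosslinks collagen, was 3.41-fold higher and CDH2 was 2.57-fold lower.

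Heat shock genes of the membrane had a median of -0.14 at percentile 2.03, although HSPB1 was 12.8-fold higher and HSP90AB1 2.19-fold lower, and under spike-in scaling the median was 0.80. The call was lost under spike-in scaling, with the mean of all probe sets and without probe sets of suffix x or s. Ribosomal protein genes had a median slightly above 0, at 0.07, that lay low among matched random lists at percentile 1.28, with 35 of 35 within 2-fold. It was -0.25 under loess normalization, and the call was lost under quantile normalization.

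The 11 other chicken lists lay within the range of random lists in the chosen setting. The medians were -0.02 for glycolysis, 0.37 for hypoxia response, 0.21 for netrins and receptors, 0.21 for collagens and fibroblast matrix, -0.23 for endothelial cells and 0.19 for interferon response. They were 0.74 for immediate early genes, 0.06 for unfolded protein and amino acid stress, -0.10 for cholesterol synthesis, 0.27 for oxidative phosphorylation and 0.03 for chorioallantoic ion and calcium transport. Under some of the 11 alternatives endothelial cells were called lower, under 3, and glycolysis lower, under 1, while interferon response and immediate early genes were called higher under 2 each and hypoxia response under 1. Of single members, COL8A1 was 5.98-fold higher on its brightest probe set and had a log2 ratio of 1.01 on another. COL6A1 was 3.22-fold higher on its brightest probe set, but its probe sets ranged from -0.15 to 1.69. Its log2 ratio was -0.078 under quantile normalization. COL11A1 was 3.36-fold, GATA2 at least 2.76-fold and TAL1 2.59-fold lower. The endothelial receptor TEK was 2.61-fold higher on its brightest probe set and had a log2 ratio of 0.65 on its other. For the sodium channel subunit SCNN1A these values were 2.72-fold higher and 0.87. Chicken NTN1 was at least 1.71-fold lower, VEGFA had a log2 ratio of -0.41 and UNC5B of 0.33. NEO1 had 0.21 on its brightest probe set and -1.37 on the other.

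**Figure D2:**
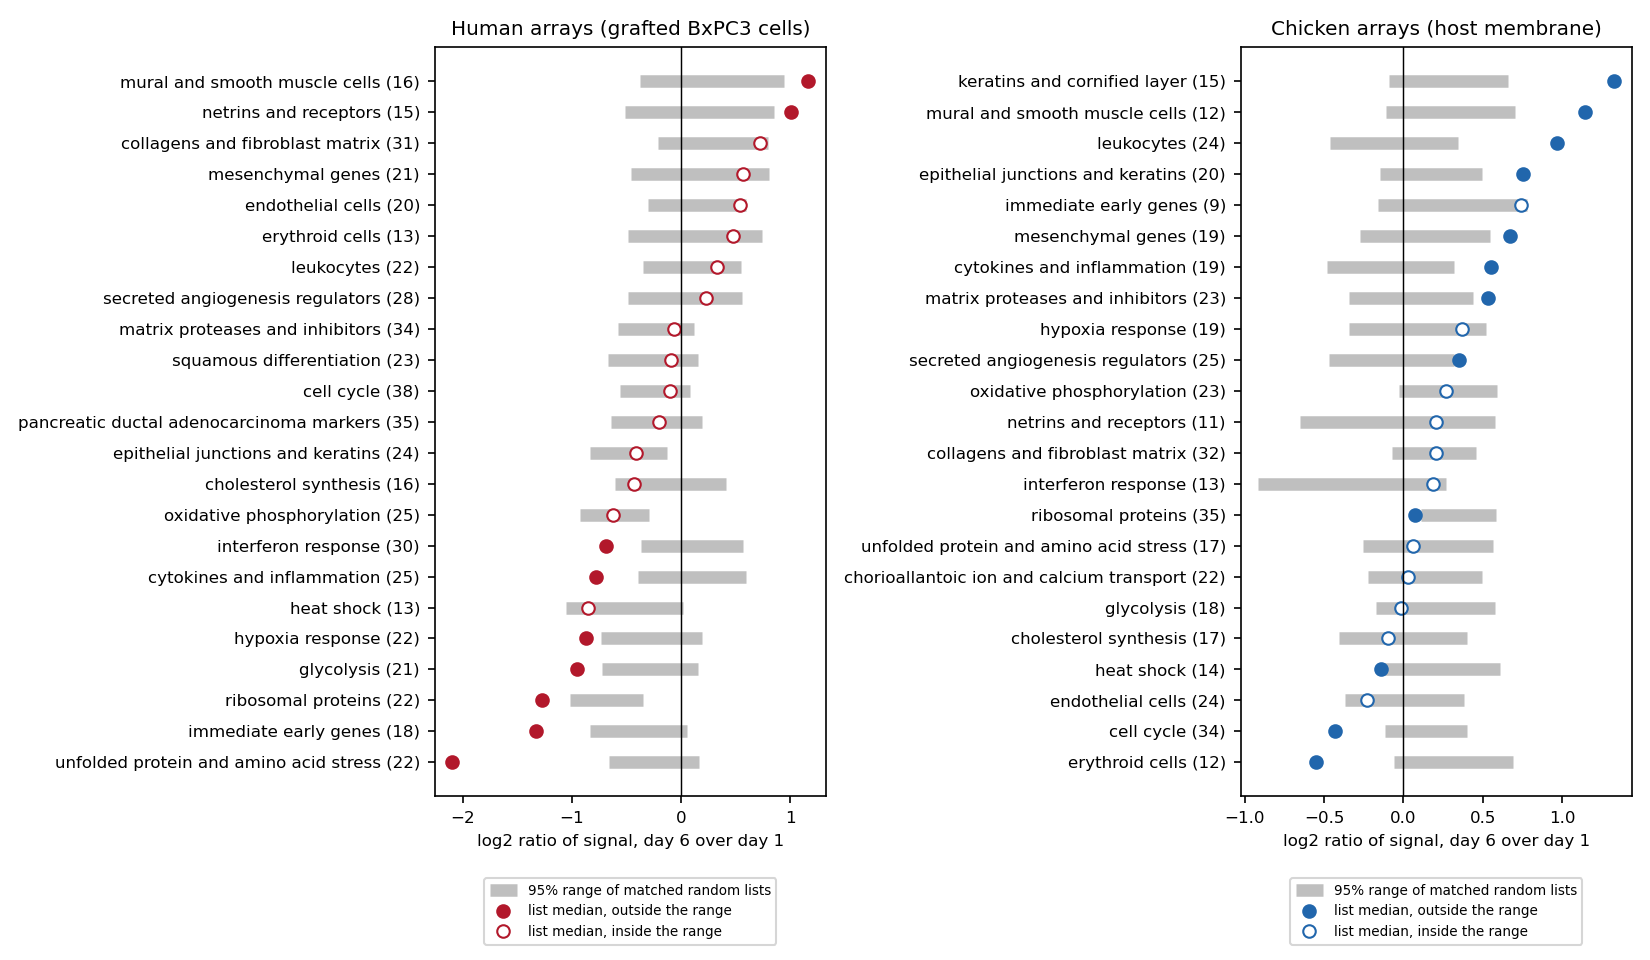
Median log2 ratio of signal, day 6 over day 1, of each fixed gene list (measured genes in brackets) on the human and chicken arrays, with grey bars for the 95% range of matched random lists and filled points outside it. The human stress list sits at -2.09 and the chicken keratin list at 1.33.

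Of 10775 measured chicken genes 1042 were higher and 1452 were lower by 2-fold or more, of which 769 and 601 were above the floor on both arrays. Higher genes made up 41.8% of these, against 53.0% under quantile normalization and 54.5% under loess normalization. The share was 73.1% with the floor at the 75th percentile, 67.9% with the brighter array at 4 times the floor and 93.8% under spike-in scaling. Spike-in scaling moved the median log2 ratio of all genes from -0.06 to 0.79. Beyond the genes above, LOC770450 was 134-fold, GPIHBP1 32.8-fold, LY6CLEL 27.1-fold, the mesothelial surface protein MSLN 20.3-fold, the peptide transporter SLC15A1 17.3-fold and TSPAN8 13.9-fold higher. LOC420770 was 41.2-fold, the metalloprotease gene ASTL 35.5-fold, the protease inhibitor A2M 13.8-fold and FST, which binds activin, 9.16-fold lower. WAC was 6.47-fold lower on its brightest probe set and had a log2 ratio of -0.42 on another. SRP19 was 5.88-fold, LOC769486 5.70-fold and COL13A1 5.40-fold lower.

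The log2 ratios depended on signal strength in opposite ways on the 2 kinds of array. In the brightest signal decile the median was -0.68 on the human and 0.36 on the chicken arrays, and in the fourth human decile it was 1.04 and in the third chicken decile -0.96. All 18 human spike-in control probe sets were higher on day 6, with a median ratio of 1.38, and all 27 chicken ones were lower, with a median ratio of 0.528.

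**Figure D3:**
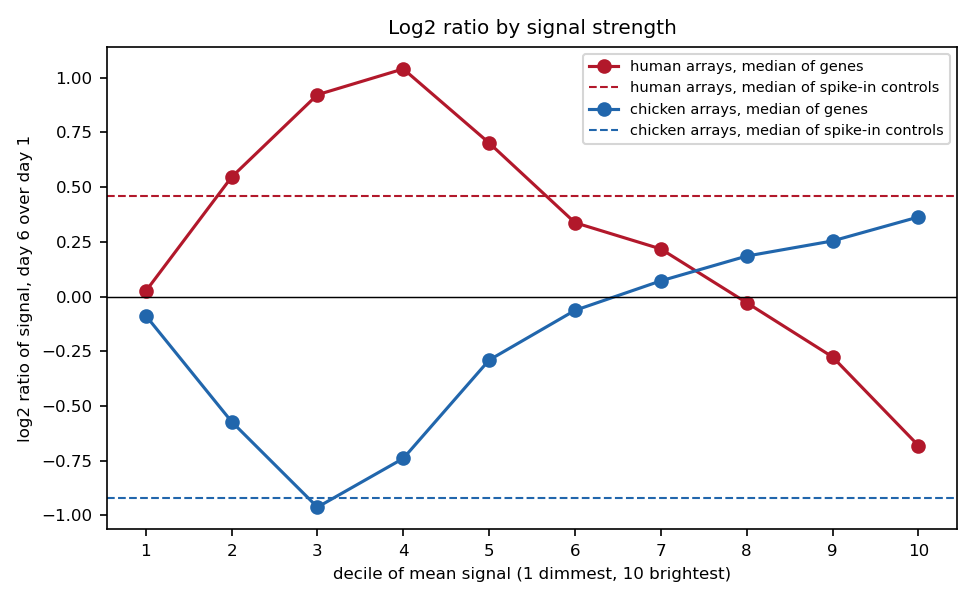
Median log2 ratio of signal, day 6 over day 1, by decile of mean signal for genes measured on the human and chicken arrays (points and lines), with the median of the spike-in controls as dashed lines. The brightest decile sits at -0.68 on the human and 0.36 on the chicken arrays.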

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

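Of the tests in this part, those on general signal loss, dim-probe background, spike-ins and RNA degradation were chosen after the results they use had been seen.

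Several results went opposite ways on the human and chicken arrays, which were scaled separately, and the differences were not tested. Differences below are the chicken minus the human log2 ratio. Where a gene lay at the floor on an array, the difference is a bound for the probe sets and scaling used. Other probe sets or settings can give a smaller difference. The cytokine and inflammation list differed by 1.33. Among genes lower on the human and higher on the chicken arrays, the difference was 3.26 for DSP, 3.28 for ELF3, 2.96 for FGFBP1, 4.53 for JUP, 3.38 for NFKBIA and 3.43 for PTGS2. It was a bound for CTSK at 3.23, DUSP1 at 6.35, HK1 at 4.54, OCLN at 3.20, SERPINB5 at 4.36 and TSPAN8 at 5.30. Among genes higher on the human and lower on the chicken arrays, it was -4.98 for L3MBTL1, and a bound for FGF1 at -2.94, HBZ at -5.95 and HGF at -2.65. The human DUSP1 value rests on a probe set that other DUSP1 probe sets contradict.

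The lower amino acid and endoplasmic reticulum stress list of the human cells could come from a loss of signal that lowers all bright genes alike. Loess normalization, which removes the trend with signal, moved the list median from -2.09 to -1.21, still below all 10000 matched random lists, which argues against this as the whole cause but leaves it open for part of the size. A further list of the same programme, tRNA synthetases and amino acid transport, lay at percentile 0.03. It was chosen after the data had been seen, though before its own result was. As it was read on the same 2 arrays, it is no independent check and cannot tell causes apart. A stress programme that was higher 1 day after grafting is a hypothesis that stays open. Whether handling, the new site or chance between pools set it was not tested.

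The higher mural and smooth muscle markers on the human arrays could reflect chicken RNA binding to human probes, since the same list was higher on the chicken arrays. Over 12 of its genes found on both arrays the rank correlation of the ratios, across genes that are not independent replicates, was 0.45, below the upper limit of 0.50 for random gene sets and above 0, so this cannot be told apart with so few genes. HBZ was at least 19.2-fold lower on the chicken and 3.23-fold higher on the human arrays. It is an erythroid gene outside the mural list and was picked for going opposite ways, so it cannot decide this for the list. A higher background of dim probes on day 6 cannot be told apart either. The list lay above its random range in 9 of 12 settings, but these settings are not equally telling. Values as deposited and median scaling nearly repeat the chosen setting, with medians of 1.16 and 1.19. The call was lost under quantile and loess normalization, which act on the trend with signal, at percentiles 93.7 and 96.3. It was also lost with the floor at the 75th percentile, at percentile 86.7, so the count of settings cannot decide this. No biological explanation was tested.

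The opposite trends with signal strength may come from a smaller human share of the pooled RNA on day 6. The spike-ins had a median log2 ratio of 0.46 on the human and -0.92 on the chicken arrays, which such a share would give, but these values were known beforehand and a different amount of labelled RNA on each array would give them too, so the 2 cannot be told apart. More degraded RNA on day 6 stays open, but most control ratios of 3' to 5' signal run against it, from 2.13 to 1.27 for human actin, 1.45 to 1.15 for human GAPDH and 4.17 to 2.86 for chicken actin, while 1 of 4, chicken GAPDH, was slightly higher at 1.05 and then 1.08, and such ratios have no known spread here. No biological explanation was tested.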

How the results depend on the processing

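The spike-in scaling and the minimum of 4 times the floor were chosen after the data had been seen. No paired analysis was possible because each group holds 1 array. Of the lists called on the human arrays 3 of 9 kept their call under all 11 alternatives, and of those on the chicken arrays 6 of 12. Signals near the floor limit most human genes that were higher, and counts depended on the floor by its construction; for the other values below the cause was not tested. Human genes higher and lower numbered 4868 and 3531 with the floor at the 25th percentile, 637 and 1222 at the 75th, 5504 and 3807 with no floor, 988 and 729 at 3-fold, 1680 and 3934 under spike-in scaling, and 903 and 1309 with the brighter array at 4 times the floor. Chicken genes higher and lower numbered 1916 and 2628 with the floor at the 25th percentile, 632 and 233 at the 75th, 2078 and 2976 with no floor, 292 and 327 at 3-fold, and 4307 and 285 under spike-in scaling. Under loess normalization 1155 chicken genes were higher and 965 lower, and with the brighter array at 4 times the floor 699 were higher and 331 lower. The spread between probe sets was 1.15 for human and 0.998 for chicken genes with the floor at the 25th percentile, and 1.65 and 1.68 with no floor.

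Lists without a call changed the sign of their median under at least 1 alternative in 8 of 14 cases on the human and 7 of 11 on the chicken arrays. Among lists with a call and named genes past the size rule, the values that changed sign were, on the human arrays, ribosomal proteins at 0.00042 under quantile and 0.21 under loess normalization, and DUSP1 at 1.39 under quantile normalization and 1.23 both with the floor at the 25th percentile and with no floor. UNC5C was -0.60 with the floor at the 25th percentile and with no floor, -0.39 with the floor as a pseudocount and -1.07 under spike-in scaling. ANKRD37 was 0.17 with the floor at the 25th percentile and with no floor, and 0.12 with the floor as a pseudocount. RPS6 was 0.25 and BUB3 1.61 without probe sets of suffix x or s, and NEO1 was -1.34 under spike-in scaling. On the chicken arrays ribosomal proteins were -0.25 under loess normalization and matrix proteases and inhibitors -0.078 with the floor at the 25th percentile, and COL6A1 was -0.078 under quantile normalization. Under spike-in scaling cell cycle genes were 0.49, erythroid genes 0.37 and heat shock genes 0.80.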

Other observations

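The 3 lists in this part, and the gene pairs across species, were chosen after the data had been seen.

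Genes that handle amino acids and oxidants were lower on day 6 in the human cells. Of 25 tRNA synthetase and amino acid transport genes 15 were lower and 2 were higher, with a median of -1.12. This median was -0.74 under quantile and -0.78 under loess normalization. The transporter genes SLC7A5 and SLC3A2 were at least 11.1-fold and 5.10-fold lower, and the glycyl-tRNA synthetase gene GARS1 was 3.47-fold lower. Of 21 oxidative stress defence genes 10 were lower and none was higher, with a median of -0.98 at percentile 0.11. The median of these genes was smaller in size under quantile and loess normalization, at -0.43 and -0.42. AKR1C1 was 5.89-fold, PRDX1 3.60-fold and the thioredoxin reductase gene TXNRD1 2.18-fold lower. Metallothioneins, which bind zinc and copper, had 7 of 8 members lower and a median of -3.52, but this list was written because its members stood out, and its probes are shared between near-identical genes.

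Over 8239 genes measured on both kinds of array the rank correlation of human and chicken log2 ratios, across genes that are not independent replicates, was -0.12. Genes higher on both numbered 118, where independent lists would give 132, and genes lower on both numbered 137 against 175. Genes higher on the human and lower on the chicken arrays numbered 214 against 164, and the reverse 159 against 141. These values were not corrected for the opposite trends with signal strength, with brightest decile medians of -0.68 on the human and 0.36 on the chicken arrays. Whether those trends account for the pattern was not tested, so it cannot be read as tumour and host genes moving in opposite directions.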
